A study of Mus musculus with 6 samples.

How the data were processed

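RNA was measured by sequencing in 6 libraries of the mouse mammary carcinoma cell line E0771. The labels place 3 libraries in a vector control group and 3 in a group expressing wild-type Malt1 (Malt1-WT), all without a stimulus. Each group and replicate number was taken from the sample title.

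Per the labels' protocols, total RNA was extracted with RNAiso Plus, libraries were made with the NEBNext Ultra II Directional kit, and paired-end sequencing was done on a NovaSeq. Trim Galore 0.6.0, STAR 2.7.3a, featureCounts 1.6.3 and the mouse build GRCm38.p6 (mm10) are named in the submitters' processing notes. The gene annotation and the strand setting of the counting are not given in the sources used here. Reads from genes that overlap on opposite strands can therefore not be assigned with certainty, nor can reads shared by near-identical gene copies.

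The authors deposited 1 table with 55571 gene symbols, of which 28089 had no count in any library. Per the file headers and the values, it holds raw counts, 1 column per library, with no normalisation. Symbols in the form of dates, which spreadsheet programs make from some gene names, fill 26 entries, and 2 of these symbols occur on 2 entries each. They were kept as separate features and are not named in the text. The authors also deposited a log2 fold change and a mean log2 expression value per gene from their own comparison, per the file headers. A score for each gene, the t statistic of the authors' comparison, is 0 for all 50005 genes with an absolute log2 fold change under 1 and for 0 genes above it. The p-value and adjusted p-value columns are the authors' own, per the file headers, and the tool that made them is not given in the sources used here.

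Total counts per library ranged from 17601656 to 20543778. The 10 most abundant genes held 5.14% to 5.57% of the counts of a library, and mitochondrially encoded genes held 2.07% to 2.32%. Every pair of libraries within a group differed by more than sampling noise in a chi-square test over genes (2.19 to 3.03 per degree of freedom, against 110 to 122 between groups), so all 6 were kept as separate replicates. Nothing in the labels says that the libraries of a group came from separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

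Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group given and a minimum count of 10, which left 13594 genes. Libraries were scaled by TMM, with factors from 1.02 to 1.03 in the vector control and from 0.973 to 0.976 in Malt1-WT. Dispersions and the quasi-likelihood model were fitted with the robust option, and each gene was tested with glmQLFTest for Malt1-WT against vector control, without a block. Adjusted p-values are Benjamini-Hochberg values, and a gene was called changed at an adjusted p under 0.05. Expression is given as TMM-scaled CPM (counts relative to a fixed library total), as mean ± SD over 3 libraries. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F statistic.

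Before the data were examined, 26 gene lists were fixed, as were the tests, the rule for naming genes and all alternatives other than the one named at the end. Each list with at least 5 tested members was tested with camera in limma 3.58.1 on TMM log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and p-values were adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, were the alternatives. Malt1 was in no list. Several lists share members, among them the NF-kB, cytokine and Regnase-1 or Roquin lists. The genes named are Malt1, the 12 largest increases and 12 largest decreases, up to 4 members with the largest change in each list, and the 3 most abundant genes. The largest changes were taken among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, and all 3 libraries of one group above all 3 of the other, leaving out predicted genes and pseudogenes. Other genes, such as the few exceptions within a list, were named after their values were seen. The results of some genes that this rule would name are not reported here.

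Gene positions, GC content and transcript length were taken from the GENCODE M21 annotation of GRCm38, which gave a length and GC content for 99.6% of the tested symbols. A separate reference list of gene names held 99.8% of the tested symbols. The M21 annotation may differ from the one used for counting.

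The tests were also run on simulated counts for Malt1-WT against vector control. These counts were drawn from the means, library sizes and fitted dispersions of the real libraries. They held 200 changed genes, and 13354 genes were tested. The share recovered was 62% of the genes changed 1.2-fold, 74% at 1.5-fold, 76% at 2-fold and 94% at 4-fold, with 5 false calls (3.16% of calls). Changed genes that the filter removed count as not recovered. As many genes were raised as lowered, whereas 61.2% of tested genes were called changed in the real libraries. Recovery, false calls and scaling under such widespread change were therefore not tried. None of the 26 lists was called when the changed genes were scattered, and a cell cycle list lowered 1.5-fold was called. Simulated genes were drawn independently of one another. This run therefore cannot show how the list tests behave when genes vary together, as they do in real libraries.

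The alternatives were scaling by DESeq2 size factors, by the upper quartile or by library size only, Malt1 left out of the library totals, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, an adjusted p of 0.01, and voom weights in the list tests. After the data were seen, an edgeR test against a 2-fold change (glmTreat) was added. Intervals of count ratios are exact 95% intervals and cover counting error only. Other tests used scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.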

Results

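Gene expression was measured by RNA sequencing in E0771 cells, a mouse mammary carcinoma line, that carried either an empty vector (3 libraries) or wild-type Malt1 (3 libraries), both without a stimulus. Malt1 encodes a paracaspase, a scaffold and protease that works with Bcl10 and CARD proteins upstream of NF-kB. The comparison asks which genes differ in expression between the cells with introduced Malt1 and the vector cells. Total counts were 17615241, 19874209 and 19648650 in vector control replicates 1 to 3 and 18408657, 20543778 and 17601656 in Malt1-WT replicates 1 to 3.

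Malt1 itself (chromosome 18, positions 65430938 to 65479067, plus strand, GRCm38) was counted at 30.0 ± 1.32 CPM (SD, n = 3) in the vector control and 305 ± 6.49 CPM in Malt1-WT (SD, n = 3). The counts per library were 517, 633 and 611 in the vector control and 5526, 6176 and 5087 in Malt1-WT. The log2 fold change was 3.34 (SE 0.042, edgeR quasi-likelihood adjusted p = 4.1e-50), a 10.2-fold difference. Counts per gene cannot separate the introduced from the endogenous Malt1 transcript.

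In Malt1-WT, 32 of 37 tested cytokine, chemokine and growth factor genes, 34 of 35 interferon-stimulated genes and all 15 MHC class I antigen presentation genes were higher, while 30 of 31 cell cycle genes, 14 of 17 histone genes and 26 of 27 genes of cholesterol and fatty acid synthesis were lower. Camera with a preset correlation called these 6 lists, but their adjusted p was 0.0514 to 0.0656 with an estimated correlation. Among genes with a mean log2 CPM of at least 1, the largest increases were in the chemokine Ccl3 (2.17 ± 0.404 to 497 ± 22.2 CPM, SD, n = 3 per group) and in Tnf (1.12 ± 0.204 to 245 ± 4.03 CPM). Il1a rose from 2.54 ± 0.370 to 497 ± 20 CPM and Cxcl9 from 0.828 ± 0.196 to 159 ± 1.14 CPM. Ccn5, a matricellular protein gene, fell from 18.3 ± 0.673 to 0.330 ± 0.0699 CPM, and the mitotic kinase gene Plk1 from 153 ± 7.08 to 27.0 ± 1.28 CPM.

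Of 13594 tested genes, 8320 (61.2%) were changed at an adjusted p under 0.05 in the edgeR quasi-likelihood test, 4210 higher and 4110 lower in Malt1-WT. A change of at least 2-fold was seen for 1783 of them, 1135 higher and 648 lower. Large changes were mostly increases, with 177 genes at least 8-fold higher and 18 at least 8-fold lower. In a test against a 2-fold change, chosen after the data were seen, 1077 genes passed, 734 higher and 343 lower. The 3 libraries of one group lay entirely above those of the other in 64.4% of tested genes, where chance gives 10%. The first principal component held 82.6% of the variance and separated the groups. The spread within groups, which edgeR names the biological coefficient of variation, was 0.0335. It may be technical, since the labels do not say that the libraries came from separate cultures.

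**Figure D1:**
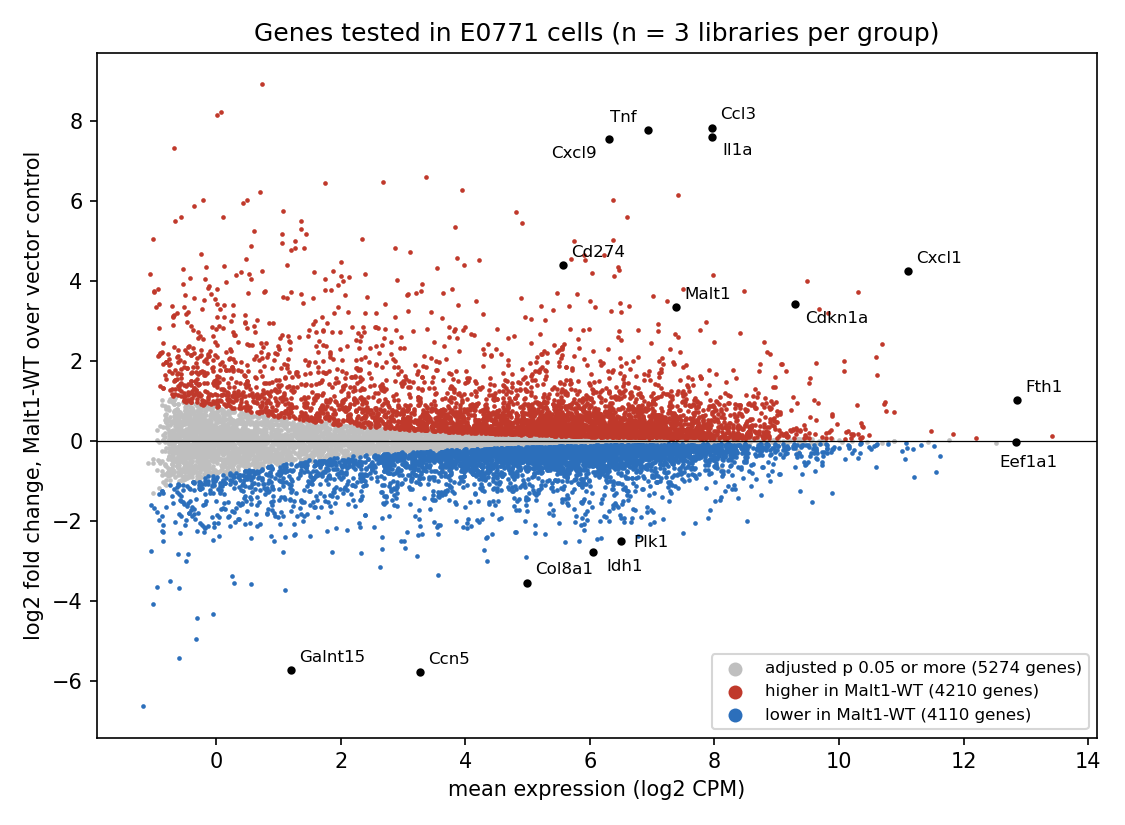
Log2 fold change of Malt1-WT over vector control (y axis) against mean log2 CPM (x axis) for the 13594 tested genes, with genes higher in Malt1-WT in red (4210), lower in blue (4110) and not past the adjusted p of 0.05 in grey, and named genes as black points. The increases reach further than the decreases, with Ccl3 at 7.84 and Ccn5 at -5.77, and some genes of low expression lie beyond both.

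The 12 largest increases were taken among genes with a mean log2 CPM of at least 1, leaving out predicted genes and pseudogenes. After Ccl3 (log2 fold change 7.84, SE 0.063), Tnf (7.78, SE 0.075), Il1a (7.62, SE 0.060) and Cxcl9 (7.56, SE 0.088) came Fgf23 (6.48), Il1b (6.47), the myeloid receptor gene Pilra (6.28), the neutrophil chemokine gene Cxcl2 (6.15), Csf2 (6.04), the tryptophan-catabolising enzyme gene Ido2 (5.75), the guanylate-binding protein gene Gbp4 (5.72) and Csf3 (5.60). All had an edgeR adjusted p of at most 1.71e-16. Il1b, Ido2 and Fgf23 rest on few control counts, 1, 1 and 2 for Il1b, 2, 2 and 0 for Ido2 and 1, 4 and 3 for Fgf23, so their size is uncertain. The plot of expression in each library shows single libraries of both groups well apart for Tnf, Il1a, Ccl3 and Cxcl9. Tnf lies on chromosome 17 (35199381 to 35202007, minus strand), Ccl3 on chromosome 11 (83647844 to 83649355, minus strand), Il1a on chromosome 2 (129299610 to 129309972, minus strand) and Cxcl9 on chromosome 5 (92321347 to 92328079, minus strand).

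The 12 largest decreases were taken by the same rule. Ccn5 (log2 fold change -5.77, SE 0.196, chromosome 2, 163820861 to 163833146, plus strand) and the mucin-type O-glycosylation enzyme gene Galnt15 (-5.73, SE 0.410) fell most. They were followed by the surface antigen gene Ly6g (-3.73), the collagen gene Col8a1 (-3.54), Rgcc (-3.34), the stromal surface glycoprotein gene Cd248 (-3.14), the DNA helicase gene Pif1 (-2.99), Olfml3 (-2.91), Akr1cl (-2.88), Arhgap33 (-2.81), the NADP-dependent isocitrate dehydrogenase gene Idh1 (-2.78) and Sema3d (-2.78). All had an edgeR adjusted p of at most 8.97e-11. Idh1 (chromosome 1, 65158616 to 65186500, minus strand) went from 115 ± 5.57 to 16.7 ± 0.775 CPM. Galnt15 had 2, 1 and 1 counts in Malt1-WT, so its size is uncertain. Ly6g belongs to a family of similar genes, so its counts can be shared with other members. Rgcc was uneven within Malt1-WT, with 59, 37 and 17 counts, against 387, 411 and 421 in the vector control. Sema3d had few and uneven counts in Malt1-WT, 13, 3 and 11, against 62, 70 and 68 in the vector control.

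**Figure D2:**
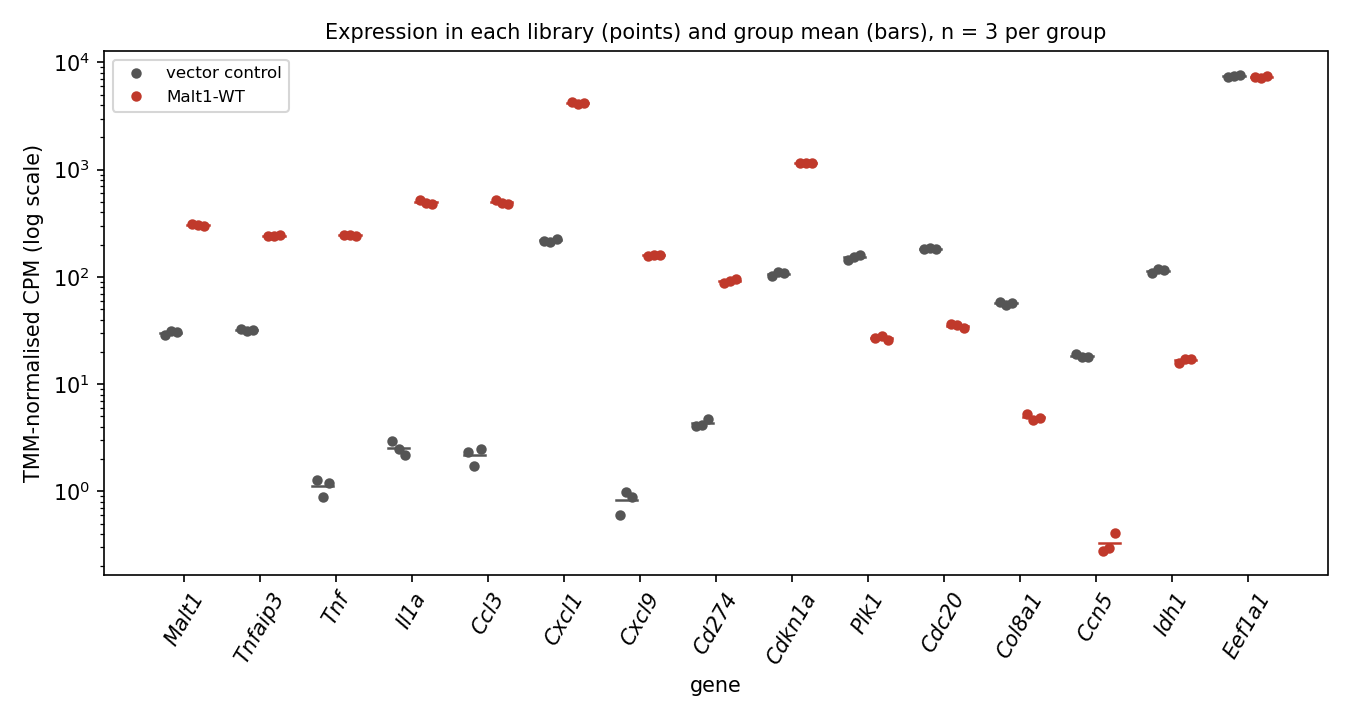
TMM-scaled CPM on a log axis (y) of 15 named genes (x), with 1 point per library, grey for vector control and red for Malt1-WT, and a bar at the mean of 3 libraries. Malt1 goes from 30.0 to 305 CPM and Tnf from 1.12 to 245 CPM, while Eef1a1 is at 7464 and 7312 CPM.

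The 3 most abundant genes behaved differently from one another. The ferritin heavy chain gene Fth1 doubled (log2 fold change 1.02, SE 0.023, edgeR adjusted p = 2.6e-38). The mitochondrially encoded cytochrome c oxidase gene mt-Co1 was 0.13 higher (SE 0.021, adjusted p = 6.2e-07). The translation elongation factor gene Eef1a1 was at -0.03 (SE 0.021, adjusted p = 0.23). Eef1a1 passed as lower with upper quartile scaling (-0.05, adjusted p = 0.0345), with library size only (-0.11, adjusted p = 6.02e-06) and without vector control replicate 1 (-0.05, adjusted p = 0.0177), with up to 0.557 under other alternatives. Pseudogene copies of Fth1 and Eef1a1 can share reads with them.

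Among the 26 fixed lists, camera with the preset correlation called 20, with 16 higher and 4 lower in Malt1-WT. With an estimated correlation 0 lists passed after adjustment, while 14 had an unadjusted p under 0.05, and fry called 25. Since fry does not compare a list with other genes, and 61.2% of tested genes were changed, its calls do not set a list apart. For each list called with the preset correlation, the p from the estimated one is given beside it. Members named because they form a small count within a list were chosen after their values were seen. Adjusted over the list alone, the number of members passing was the same as over all genes in every list except those for which another count is given.

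NF-kB target genes rose almost without exception. Of 29 tested members, 28 were higher and 1, Bcl3 (-0.17), was lower, with a median log2 fold change of 1.99 (camera adjusted p = 3.9e-15, adjusted p = 0.0536 with an estimated correlation). The largest were Tnf (7.78), Cxcl2 (6.15), Csf2 (6.04) and the T-cell chemokine gene Ccl5 (4.64, from 5.79 ± 0.382 to 145 ± 7.17 CPM). Cytokines, chemokines and growth factors had the highest median of all lists, 2.31, with 32 of 37 higher, 1 lower (Tgfb3, -0.63) and 4 not past the test (34 passing when adjusted over the list alone, against 33). The camera adjusted p was 4.0e-14, with an adjusted p = 0.0526 with an estimated correlation. Il1a (7.62), Cxcl9 (7.56) and Il1b (6.47) led this list. Of 7 tested leukocyte markers 4 were higher in the same libraries, among them Adgre1 (3 and 81 counts per group) and Cd68 (log2 fold change 1.67), while the leukocyte transcripts Ptprc and Tyrobp together had 4 counts in the 3 Malt1-WT libraries, against 13474 counts of Tnf.

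Transcripts that the RNA-degrading proteins Regnase-1 or Roquin are known to destabilise also rose, with 10 of 13 higher, 1 lower and 2 not past the test (12 passing when adjusted over the list alone, against 11). The median was 1.61 (camera adjusted p = 5.6e-05, adjusted p = 0.0732 with an estimated correlation). The interleukin subunit gene Il12b (5.51, with 0, 3 and 3 counts in the vector control) and Cxcl1 (4.25, from 219 ± 8.17 to 4181 ± 66.4 CPM) were among the largest, and the single member that fell was the cyclin gene Ccnd1 (-0.85). Of the 10 higher members 7 are also in the NF-kB list, Tnf, Cxcl1 and Cxcl2 among them, so the 2 lists are not separate evidence.

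Genes listed here as encoding MALT1 protease substrates were mostly higher, with 11 of 14 up, 0 down and 3 not past the test (median 0.37, camera adjusted p = 8.7e-04, adjusted p = 0.0656 with an estimated correlation). Cleavage of their proteins was not measured. The ubiquitin-editing enzyme gene Tnfaip3 rose by 2.92 on the log2 scale (32.1 ± 0.794 to 244 ± 2.86 CPM), Relb by 1.24 and Zc3h12a, which encodes Regnase-1, by 1.13. Tnfaip3 and Relb are also in the NF-kB list, so the lists are not separate evidence. In the list of the MALT1 complex and its upstream components, 8 of 14 were higher, 2 lower and 4 not past the test (median 0.25). The ubiquitin ligase gene Traf6 (1.24), the direct MALT1 partner gene Bcl10 (1.11) and the kinase gene Prkcd (0.86) were higher, and Card14 (-1.05, edgeR adjusted p = 0.0131) and Tab1 (-0.18) lower. This list had a camera adjusted p of 0.0277 and an adjusted p = 0.113 with an estimated correlation. Its call was lost without vector control replicate 3 (adjusted p = 0.0598) and without Malt1-WT replicate 1, 2 or 3 (adjusted p = 0.0514, 0.0734 and 0.0629). Over all alternatives the adjusted p of this list went from 4.2e-05 to 0.113, and that of Card14 from 0.00331 to 0.0991. Card14, with 8 to 30 counts per library, was not called without vector control replicate 3 (adjusted p = 0.0546), Malt1-WT replicate 2 (0.0991) or Malt1-WT replicate 3 (0.0577), nor by DESeq2 (0.0828).

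Interferon-stimulated genes were higher in 34 of 35 cases, the exception being Ifi27 (-0.19), with a median of 1.18 (camera adjusted p = 4.6e-15, adjusted p = 0.0526 with an estimated correlation). Gbp2 rose from 49.1 ± 1.12 to 663 ± 9.04 CPM (3.76), Cxcl10 from 19.3 ± 0.618 to 241 ± 6.14 CPM (3.64), and Gbp3 by 2.59. Gbp genes are similar in sequence, so reads can be split between them. All 15 tested genes of MHC class I antigen presentation were higher, with a median of 0.98 (camera adjusted p = 1.5e-09, adjusted p = 0.0656 with an estimated correlation). Examples are the non-classical class I gene H2-T23 (2.26), the immunoproteasome subunit genes Psmb9 (2.18) and Psmb10 (2.10), and the peptide transporter gene Tap1 (1.91, 78.4 ± 1.44 to 294 ± 4.98 CPM). Class I genes share sequence, and Psmb9 and Tap1 overlap on opposite strands of chromosome 17 in the annotation, so their counts are not fully separate.

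Among immune checkpoint and ligand genes, 6 of 12 were higher, 1 lower (Raet1e, -0.36) and 5 not past the test (8 passing when adjusted over the list alone, against 7). Their median was 0.64 (camera adjusted p = 0.00297, adjusted p = 0.0987 with an estimated correlation). Cd274, which encodes PD-L1, rose 21.0-fold, from 4.34 ± 0.375 to 91.6 ± 4.06 CPM (chromosome 19, 29367455 to 29388095, plus strand). The poliovirus receptor gene Pvr rose by 2.69 on the log2 scale, to 592 ± 4.83 CPM, Tnfsf15 by 2.65 and the ICOS ligand gene Icosl by 1.52. Tnfsf15 had few counts, 9, 7 and 2 in the vector control and 31, 46 and 32 in Malt1-WT, so its size is uncertain.

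**Figure D3:**
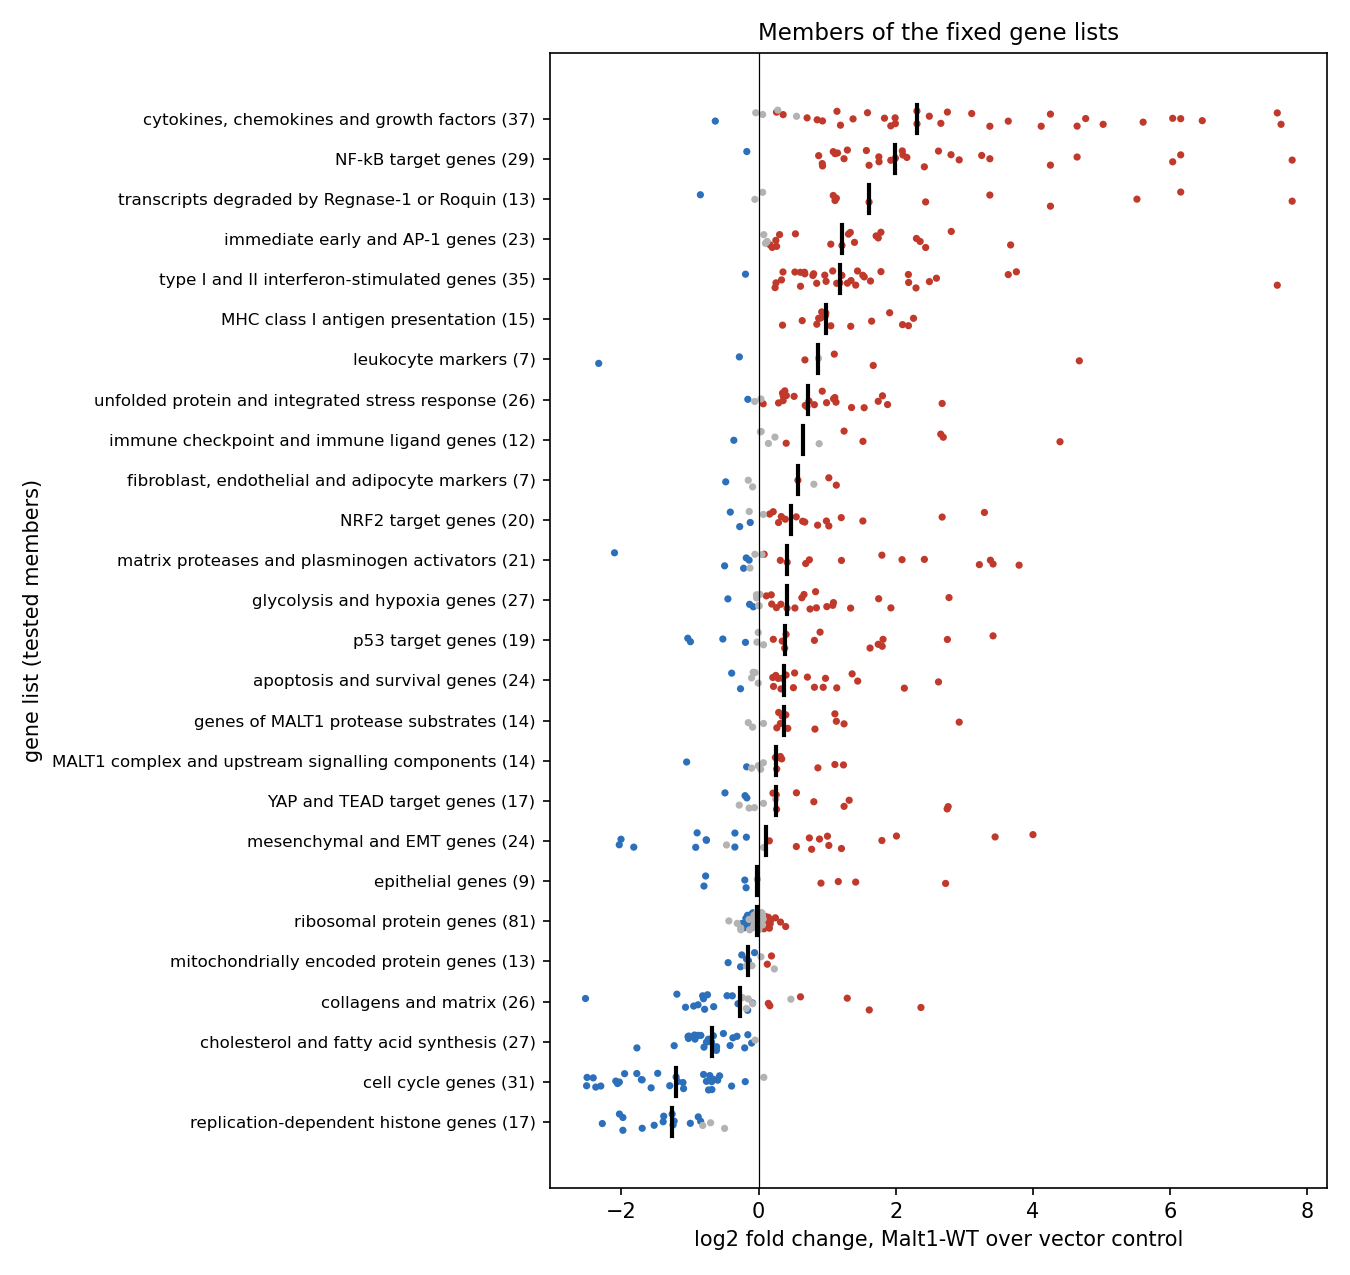
Log2 fold change of Malt1-WT over vector control (x axis) for each tested member of the 26 lists (y axis, number of tested members in brackets), red for higher, blue for lower, grey for not past the adjusted p of 0.05, with the list median as a black bar. The cytokine list has its median at 2.31 and the histone list at -1.26.

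Cell cycle genes fell together. Of 31 tested members, 30 were lower, 0 higher and 1, E2f1 (0.08), did not pass (median -1.20, camera adjusted p = 4.6e-15, adjusted p = 0.0514 with an estimated correlation). The kinetochore gene Cenpf (-2.51), Plk1 (-2.50, chromosome 7, 122159439 to 122169873, plus strand), the mitotic kinesin gene Kif20a (-2.41) and the anaphase activator gene Cdc20 (-2.37, from 182 ± 2.55 to 35.2 ± 1.72 CPM) changed most. Histone genes fell as well, with 14 of 17 lower, 0 higher and 3 not past the test (15 passing when adjusted over the list alone), and a median of -1.26 (camera adjusted p = 1.8e-04, adjusted p = 0.0656 with an estimated correlation). Hist1h1c fell from 29.4 ± 3.14 to 7.15 ± 1.32 CPM, while Hist1h4j (-2.28), Hist1h4d (-1.98) and Hist1h2bb (-1.98) were below 1 CPM in both groups. Apart from Hist1h1c and H1f0, the highest member in the vector control was Hist2h2be, at 3.51 ± 0.581 CPM. The list median thus rests mostly on genes of low expression. Near-identical histone copies can share reads, and the list also took in H1f0 (-1.39), a linker histone gene not tied to replication.

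Cholesterol and fatty acid synthesis genes were lower in 26 of 27 cases and higher in 0, with 1 not past the test (median -0.69, camera adjusted p = 2.1e-10, adjusted p = 0.0656 with an estimated correlation). The fatty acid elongase gene Elovl6 fell by 1.77 on the log2 scale (185 ± 3.51 to 54.0 ± 3.25 CPM), the mevalonate kinase gene Mvk by 1.23 and Cyp51 by 1.03.

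Targets of p53 were higher in 12 of 19 cases, lower in 4 and not past the test in 3 (median 0.38, camera adjusted p = 0.00488, adjusted p = 0.0656 with an estimated correlation). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 108 ± 5.18 to 1151 ± 11.7 CPM (3.42). The stress cytokine gene Gdf15 (2.75), Plk3 (1.81) and Plk2 (1.80) followed. The 4 lower members were Dglucy (-1.03), Sesn1 (-0.99), Ei24 (-0.52) and Rps27l (-0.19). Apoptosis and survival genes were higher in 18 of 24 cases, lower in 2, among them Casp9 (-0.39), and not past the test in 4 (median 0.37, camera adjusted p = 2.4e-04, adjusted p = 0.0656 with an estimated correlation). The members with the largest change act in opposite directions, since Birc3 (2.62) encodes an inhibitor of apoptosis, while Bik (2.12) and Tnfsf10 (1.44) encode inducers and Mlkl (1.36) the effector of necroptosis. Bik had few counts, 3, 6 and 3 in the vector control and 20, 12 and 18 in Malt1-WT, so its size is uncertain.

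Immediate early and AP-1 genes were higher in 20 of 23 cases, lower in 0 and not past the test in 3 (median 1.21, camera adjusted p = 2.2e-08, adjusted p = 0.0526 with an estimated correlation). Zfp36, which encodes the mRNA-destabilising protein tristetraprolin, rose from 8.14 ± 0.577 to 104 ± 3.12 CPM (3.67). The others with the largest change were Fos (2.81), Ier3 (2.43) and Phlda1 (2.35). Genes of the unfolded protein and integrated stress response were higher in 23 of 26 cases, lower in 1 (Slc7a5, -0.16) and not past the test in 2 (median 0.72, camera adjusted p = 4.8e-09, adjusted p = 0.102 with an estimated correlation). The cystine transporter gene Slc7a11 (2.68), Trib3 (1.88), Ppp1r15a (1.81) and Sesn2 (1.74) led them. Among NRF2 targets, 15 of 20 were higher, 3 lower (Gsta4, -0.41, Tkt, -0.28, and Taldo1, -0.12) and 2 not past the test. Their median was 0.47 (camera adjusted p = 8.6e-05, adjusted p = 0.0601 with an estimated correlation). The heme oxygenase gene Hmox1 rose from 153 ± 1.56 to 1496 ± 64.8 CPM (3.29), Slc7a11 by 2.68 and Srxn1 by 1.52.

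Glycolysis and hypoxia genes were higher in 19 of 27 cases, lower in 3 (Car12, -0.45, Pkm, -0.13, and Pgam1, -0.08) and not past the test in 5 (median 0.41, camera adjusted p = 4.4e-05, adjusted p = 0.113 with an estimated correlation). The largest changes were in the vasoactive peptide gene Adm (2.78), the glucose transporter gene Slc2a1 (1.93), Ndrg1 (1.75) and the prolyl hydroxylase gene Egln3 (1.34). The 5 that did not pass were Eno1 (-0.03), Ldha (0.02), Pgk1 (0.01), Car9 (-0.03) and Tpi1 (-0.00). YAP and TEAD targets were higher in 9 of 17 cases, lower in 3 (Ajuba, -0.49, Myof, -0.20, and Axl, -0.17) and not past the test in 5 (median 0.25, camera adjusted p = 0.0306, adjusted p = 0.109 with an estimated correlation). Ccn1 (2.76), the tissue factor gene F3 (2.75), Amotl2 (1.32) and Nt5e (1.25) were the largest, whereas the target gene Ccn2 was at 0.25 and did not pass.

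Matrix proteases and plasminogen activators were higher in 13 of 21 cases, lower in 5 and not past the test in 3 (median 0.42, camera adjusted p = 0.00452, adjusted p = 0.0656 with an estimated correlation). Mmp10 (3.80), Mmp13 (3.42), the urokinase gene Plau (3.38, from 6.53 ± 0.570 to 68.2 ± 3.95 CPM) and the tissue plasminogen activator gene Plat (3.22, from 17.8 ± 1.28 to 165 ± 1.38 CPM) rose most. The 5 lower members were Mmp19 (-2.10), Adam10 (-0.50), Mmp11 (-0.22), Ctsl (-0.18) and Ctsb (-0.14). Collagens and matrix genes fell on balance, with 15 of 26 lower, 6 higher and 5 not past the test (median -0.27, camera adjusted p = 0.0107, adjusted p = 0.198 with an estimated correlation). Thbs2 fell from 81.6 ± 0.506 to 14.2 ± 1.17 CPM (-2.52), while the laminin subunit gene Lama3 (2.37) and the collagen gene Col18a1 (1.61) rose.

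Mesenchymal genes split both ways, with 12 of 24 higher, 10 lower and 2 not past the test (23 passing when adjusted over the list alone, against 22). The list had a median of 0.11 and was not called by camera (adjusted p = 0.379), while fry called it as higher (adjusted p = 1.4e-05). The integrin subunit gene Itgb3 rose by 3.45 on the log2 scale and the matrix gene Tnc by 2.01, whereas Tgfbi fell by 2.03. Epithelial genes were also split, with 4 of 9 higher, 4 lower and 1 not past the test. Their median was -0.02 while their mean was 0.47, and the camera direction was up without passing (adjusted p = 0.505), while fry called the list as higher (adjusted p = 2.8e-05). Desmoplakin (Dsp) at 2.73, St14 at 1.16 and Ovol1 at 0.91 were among the higher members.

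Ribosomal protein genes moved little, with 17 of 81 higher, 20 lower and 44 not past the test, and a median of -0.03 (camera adjusted p = 0.505). With library size only, this list was called lower (median -0.11, adjusted p = 0.0397, against up to 0.914 under other alternatives). The largest changes past the test were Rpl22l1 (0.39), Rpl13a (0.32), Rpl10 (0.24) and Rpl7l1 (-0.24), and processed copies of these genes can share reads. Of 13 mitochondrially encoded protein genes, 2 were higher, 6 lower and 5 not past the test (median -0.15, camera adjusted p = 0.245), and fry called the list as lower (adjusted p = 0.00376). Besides mt-Co1 (0.13), mt-Nd4 (0.19) was the only higher one, while mt-Nd1 (-0.44), mt-Co2 (-0.26) and mt-Nd2 (-0.25) were among the lower. The mt-Co2 call (edgeR adjusted p = 0.0101) was lost without vector control replicate 2 (adjusted p = 0.0655) and with DESeq2 (adjusted p = 0.0609), and was down to 0.001 elsewhere.

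Camera called neither list of markers of other cell types, while fry called both as higher (adjusted p = 0.00112 for leukocyte markers and 9.7e-04 for fibroblast, endothelial and adipocyte markers). Of 16 leukocyte markers, 7 were tested, with 4 higher, 2 lower and 1 not past the test (7 passing when adjusted over the list alone, against 6), and a median of 0.87 (camera adjusted p = 0.224). Cd68 (1.67) and Coro1a (1.10) were higher and Lyz2 (-2.33) was lower, and Lyz2 has a close copy that can share its reads. Adgre1 had 3 counts in the vector control and 81 in Malt1-WT, a ratio of 28.8 (95% interval 9.5 to 142, counting error only), and the list median is the same with Adgre1 at this ratio. Coro1a was not called without Malt1-WT replicate 2 (0.76, adjusted p = 0.0803, against down to 0.00128 elsewhere). Of 7 tested fibroblast, endothelial and adipocyte markers, Fabp4 (1.13), Pecam1 (1.02) and Pdgfrb (0.57) were higher, Pdgfra (-0.48) was lower and 3 did not pass (median 0.57, camera adjusted p = 0.322).

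The authors' deposited table lists 630 genes at an adjusted p under 0.05, of which 432 were higher and 198 lower in Malt1-WT. Its t statistic is 0 for every gene with an absolute log2 fold change under 1, so the 630 are closer in kind to the 1077 genes of the edgeR test against a 2-fold change than to the 8320 changed by any amount, though the tool used is not given. Of the tested genes, 583 passed in both the authors' deposited table and the edgeR test for any change, all 583 with the same sign. Both rest on the same 6 libraries, so the match is not independent evidence. Across tested genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of the edgeR fit had a Pearson correlation of 0.997. For Malt1 the authors' deposited table gives a log2 fold change of 3.33 and an adjusted p of 4.3e-05. Among the largest increases and decreases named above, Ido2 (adjusted p = 0.0569) and Sema3d (adjusted p = 0.202) did not pass in the authors' deposited table.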

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

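The test against a 2-fold change was chosen only after the results were seen. It called 1077 genes, against 8320 for any change, because it asks for a larger difference. Camera with an estimated correlation called 0 lists (14 at an unadjusted p under 0.05), against 20 with the preset correlation, 25 with fry and 20 to 21 over the other scalings. Leaving out 1 library at a time gave 7878 to 8074 changed genes, 3959 to 4081 higher, 3880 to 4040 lower, 1831 to 1889 changed at least 2-fold, 19 to 20 lists and a Malt1 log2 fold change of 3.30 to 3.37. Other counts of changed genes were 8321 with DESeq2 size factors, 8360 with the upper quartile, 8320 with Malt1 left out, 8345 without a filter, 8063 with the stricter filter, 7198 at an adjusted p under 0.01, 7294 with DESeq2 and 8317 with limma-voom. Library size only moved the median gene by -0.0761 and gave 3528 higher and 5006 lower, so 41.3% of calls were higher, against 50.6%. Among the named genes, the calls that changed were those of Card14, mt-Co2, Coro1a and Eef1a1, given with the results. Calls of other genes changed as well. Of the 8320 genes, 7638 were also called with library size only, 7065 with DESeq2 and 7632 without vector control replicate 3. The collagen and YAP lists lost their call at a threshold of 0.01 (adjusted p = 0.0107 and 0.0306), as did the MALT1 complex list. No list or named gene changed direction while past the threshold. With the replicate block, 8168 genes were changed (4134 higher, 4034 lower), 8147 of them also called without it, and it changed no call of a list or named gene. Same-numbered libraries had deviation correlations of -0.026, -0.021 and 0.017, and not every library correlated best with its own number. Alternatives meant for normalised values were not run, since the table holds counts. Card14 and Coro1a had few counts and uneven replicates, and the cause of their lost calls was not tested.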

Other observations

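The gene families below, the test of Ptprc and Tyrobp, the test of mitotic against replication genes and the counts of genes in other splits were chosen only after the results were seen. Of 379 families of genes sharing a symbol stem, 17 were enriched among genes changed at least 2-fold in a Fisher test (758 tests). All 9 tested guanylate-binding protein genes (Gbp) were at least 2-fold higher (median 3.76, adjusted p = 8.6e-08), Gbp5 going from 24.5 ± 1.35 to 340 ± 17.4 CPM (SD, n = 3 per group). Interleukin and interleukin receptor genes were at least 2-fold higher in 18 of 38 cases (adjusted p = 8.6e-08), among them Il6 (17.6 ± 1.31 to 182 ± 4.36 CPM) and Il23a (6.45 ± 0.660 to 83.2 ± 7.92 CPM). Small proline-rich protein genes (Sprr), which encode precursors of the cornified envelope of squamous epithelia, were at least 2-fold higher in 5 of 7 cases, 1 of them the pseudogene Sprr2j-ps (median 3.70, adjusted p = 0.00555), with Sprr2d at 4.73 and Sprr2e at 3.70, while Sprr1a (0.30) and Sprr1b (-0.59) did not pass. TNF receptor family genes were at least 2-fold higher in 6 of 13 cases (adjusted p = 0.0173), with Tnfrsf1b rising from 164 ± 2.91 to 762 ± 9.12 CPM and Tnfrsf9, which encodes 4-1BB, from 56.3 ± 3.93 to 191 ± 5.46 CPM. Among the kinesin genes (Kif), 11 of 28 were at least 2-fold lower (adjusted p = 5.1e-06), with Kif2c at -2.45. Each of the 17 medians kept its sign under the other scalings. The families rest on the symbol alone, and members with similar sequence, such as the Gbp genes, can share reads. The Fisher test treats members as independent, which genes that vary together are not, so its p-values may be too small. Several families, the Gbp and interleukin genes among them, share members with the fixed lists and are not separate evidence.

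Of the interferon genes, 3 were looked at. Ifnb1 had 4 counts in the vector control and 42 in Malt1-WT (ratio 11.2, 95% interval 4.06 to 42.9, counting error only), Ifna4 had 0 and 3, and Ifng had 0 in both groups.

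Inflammatory genes were higher in Malt1-WT, and 3 technical explanations were tested. After a trend on GC content and transcript length was removed, the median of the NF-kB target list was 2.04, against 1.99 before, and its lowest value over 4 other scalings was 1.92, so neither accounts for the increase. Leukocytes in the cultures were tested first by the share of tested markers that were higher, and that criterion, at least 50%, was met with 4 of 7. A second test, made after those values were seen, set Ptprc and Tyrobp, abundant in leukocytes, against Tnf, and they had 4 counts, 0.0297% of the 13474 Tnf counts, while the 9 markers too low to test had 37 counts in Malt1-WT and 46 in the vector control. These values argue against leukocytes as the source, and the introduced Malt1 may underlie the increase, a hypothesis that this design cannot separate from other differences between the 2 cell lines.

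Cell cycle genes were lower in Malt1-WT. The list median was -1.22 after the GC and length trend was removed, against -1.20 before, and its highest value over the other scalings was -1.20, so neither accounts for the decrease. Within the list, 17 mitotic genes had a mean log2 fold change of -1.84 (SD 0.53) and 14 replication genes -0.69 (SD 0.38), with a permutation p of 2e-05, the smallest that the resamples can give. Since the list was divided after the largest decreases were seen to be mitotic genes, and such genes vary together, this p restates the difference and does not test it. Culture density and growth rate of the 2 lines stay open and were not tested.

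Change was spread over the genome, with 8320 genes called. Chromosome of origin held 0.282% of the variance of the log2 fold changes, against 0.208% on average when permuted (permutation p = 0.13). This used 9142 genes with a mean log2 CPM of at least 3, with log2 fold changes of a size above 2 cut to 2. These values argue against whole-chromosome dosage as the main source. Akr1cl (-2.88) and Idh1 (-2.78) are neighbours on chromosome 1 and both among the 12 largest decreases named, and the median of the 7 other tested genes within 500 kb of Idh1 was -0.26. That median was meant to decide on a lost segment, but the other genes lie outside the stretch from Akr1cl to Idh1 except Gm8550, which lies inside Akr1cl and had 0 counts in Malt1-WT. A lost segment of only that stretch may thus be present and cannot be told apart from regulation, although Idh1 kept 16.7 CPM and its neighbour Pikfyve was at 0.25.

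The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of the 10, gave 8320 changed genes, 4210 higher, 4110 lower and 1783 changed at least 2-fold, and the highest of the other 9 was 0 for each with edgeR (73 to 141 genes at an unadjusted p under 0.05, and 0 with limma-voom). For the lists, the real split gave 20 calls with the preset correlation and the highest other 13. Each of the other 9 splits has 2 libraries of one group and 1 of the other on each side. Part of the real difference thus stays in its contrast, and the rest adds to the spread within its sides. Neither the gene counts nor the list counts of these splits therefore show what is called without a difference. With an estimated correlation camera called 0 lists in the real split.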
